A study of Arabidopsis thaliana with 2 samples.

How the data were processed

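Per the labels' protocols, plants were grown in continuous light at 20 °C, siliques of 1.1 to 1.4 cm were taken from plants 38 to 46 days old, and seeds were fixed in ethanol and acetic acid and embedded in paraffin. Regions were chosen by morphology on sections, cut by laser and pooled over seeds, and the number of seeds or plants behind each library is not given in the sources used here. Total RNA, 15 ng per library, was amplified to cDNA, 150 ng of double-stranded cDNA entered an Illumina library, and the library was enriched by 15 cycles of PCR, so reads carry amplification noise that counting error does not include. There are 2 libraries, 1 of the embryo proper and 1 of the suspensor, grouped by the tissue named in the labels.

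The deposited values are RPKM, reads per kilobase of gene and per 1000000 reads, per the file headers, with 3 decimals, and the authors listed a gene only where its value was above 0. The submitters' processing notes name HISAT2 2.0.6, HTSeq 0.6.1 and the build TAIR10 without giving their roles. Strand, reads with several matches and the gene length behind the RPKM are not given in the sources used here. RPKM is a share of the library, so a few very abundant transcripts lower the values of all others; alternative scalings were run for this reason.

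Gene symbols, products and coding lengths came from the RefSeq annotation of the assembly TAIR10.1. Of 20029 identifiers listed in either library, 19875 matched its locus tags; 110 of the 154 others were organelle genes. The assembly differs in name from that of the files and the files carry no positions, so no genome coordinates are given.

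Reads were recovered from the RPKM. The product of RPKM and the longest coding length, summed over genes, came to 1001080 in the embryo proper and 1001890 in the suspensor, close to the 1000000 that coding lengths would give, and the value of 1 read was then found by a search for the step at which low values become whole numbers. Among values of at least 0.2 RPKM and at most 15 reads, 91.8% in the embryo proper and 92.1% in the suspensor were within 0.05 of a whole read, and 96.6% and 96.9% among genes with a single model, where chance gives 10%. The totals were 12716051 and 7189153 reads assigned to genes, a ratio of 1.77, with medians of 145 and 88 reads per listed gene. The form of this search was settled after the values had been seen. Genes with 1 read are listed, 516 and 644 of them among genes with a single model, so an unlisted gene was taken as 0 reads where a bound is given. The floor of an unlisted gene is 3 reads in that library. Thinned to the depth of the suspensor, the embryo proper library kept a mean of 17470 genes with a read over 20 draws, against 17934 unthinned and 18535 in the suspensor.

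The main measure was log2 of the suspensor to embryo proper ratio after adding a pseudocount of 1 RPKM, which understates the difference of low genes; folds printed with an interval are ratios without the pseudocount. Genes counted at 4-fold were listed in both files with at least 1 RPKM in at least 1. Choices made before the data were examined were the pseudocount, the filter, the thresholds, 18 lists of named genes and 8 lists defined by words in the annotation, and the alternatives below other than those said to be added. The lists covered embryo proper and shoot pole regulators, root pole and vascular precursors, suspensor genes, protoderm and cuticle, maturation regulators, storage proteins, cell cycle, DNA methylation and small RNA, gibberellin, auxin, cytokinin, photosynthesis, transport, cell death, heat shock, endosperm, seed coat and reference genes. Those defined by annotation were ribosomal proteins, histones, wall-loosening proteins, lipid transfer proteins, cytochrome P450, small cysteine-rich proteins, F-box and pentatricopeptide repeat proteins. By the same rules, 4 members whose symbol and locus did not match the reference were left out, KIR1, VPE3, HSP70-4 and HSP22. The lists share members, among them PIN7 in the suspensor and auxin lists, SUC5 in the transport and endosperm lists and LEC1 in the maturation and histone lists.

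For each list, members with at least 1 RPKM in at least 1 library were counted at 2-fold, and the median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean expression; below the percentile 2.5 or above 97.5 it was said to stand apart. Named genes were the 12 with the largest difference each way among nuclear protein-coding genes of at least 10 RPKM, the 5 most abundant of each library, and list members with large differences or high levels; not each of these is printed.

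Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter and a filter of 10 RPKM, scaling to a sum of 1000000, to a median log2 ratio of 0 and by the upper quartile, thresholds of 2-fold and 8-fold, and random lists also matched on gene length. Added after the data were seen were unlisted genes counted as 0, the 10 most abundant genes left out of the scaling, and, for the lists and the correlation, a minimum of 20 recovered reads, which for the gene counts had been set before. The steps were tested on simulated libraries of embryo proper and suspensor with counting error only. Over 16604 genes, 200 were changed 8-fold, and 100% of these and 2 unchanged genes were called. The 200 were drawn from genes with a mean of at least 10 RPKM, so recovery at lower levels was not tested. Read totals were recovered within 0.000138%, with the same coding lengths used to simulate and to recover, so an error in gene length was not tested. Of 100 random lists of 15 genes without a shift, 5 stood apart, and of 100 lists shifted by 2 on the log2 scale 99 did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9 and blastn 2.17.0 were used.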

Results

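Transcripts were measured in the 2 parts of the globular Arabidopsis thaliana embryo, in the accession Ws-0. The embryo proper is the apical sphere that forms the seedling, and the suspensor is the stalk below it that joins the embryo to the maternal tissue. Each part was cut by laser from paraffin sections of 5 or 7 μm, from seeds whose embryo proper measured 24 to 32 μm across, and each gave 1 library. The question was which genes differ in transcript level between the parts. The embryo proper library listed 18071 genes and held 12716051 reads assigned to genes, and the suspensor library listed 18672 genes and held 7189153, both totals being recovered from the deposited values. With 1 library per part there was no replicate check, so no test was run and no p-value is given, and each value describes these libraries. Intervals after a fold are 95% exact binomial intervals from the recovered reads and, because amplified reads without molecular identifiers are not independent molecules, they cover counting error only.

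The embryo proper library was higher for regulators of the shoot pole, for dividing-cell genes and for the machinery of translation, and the suspensor library was higher for WOX8 (AT5G45980) and other basal lineage genes, for nutrient transporters and for small cysteine-rich proteins, and also for all 10 measured endosperm markers and 10 of 12 seed coat markers. Of 15815 genes listed in both files with at least 1 RPKM in at least 1 of them, 1784 were at least 4-fold higher in the suspensor and 1229 at least 4-fold higher in the embryo proper, on the scale of log2(RPKM + 1). A further 311 genes listed in the suspensor library alone and 184 listed in the embryo proper library alone passed the same threshold with the unlisted value taken as 0. Genes with at least 1 RPKM numbered 15021 in the embryo proper and 15759 in the suspensor, with 13805 shared, 1216 in the embryo proper only and 1954 in the suspensor only. Across genes, log2(RPKM + 1) had a Pearson correlation of 0.70 and a Spearman correlation of 0.67 between the libraries, and genes are not independent replicates. In 20 simulated pairs of libraries that differed by counting error alone, at most 1 gene passed the 4-fold threshold in each direction. These were drawn for the 16604 genes listed in both files that had a coding length, with the same filter of 1 RPKM.

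**Figure D1:**
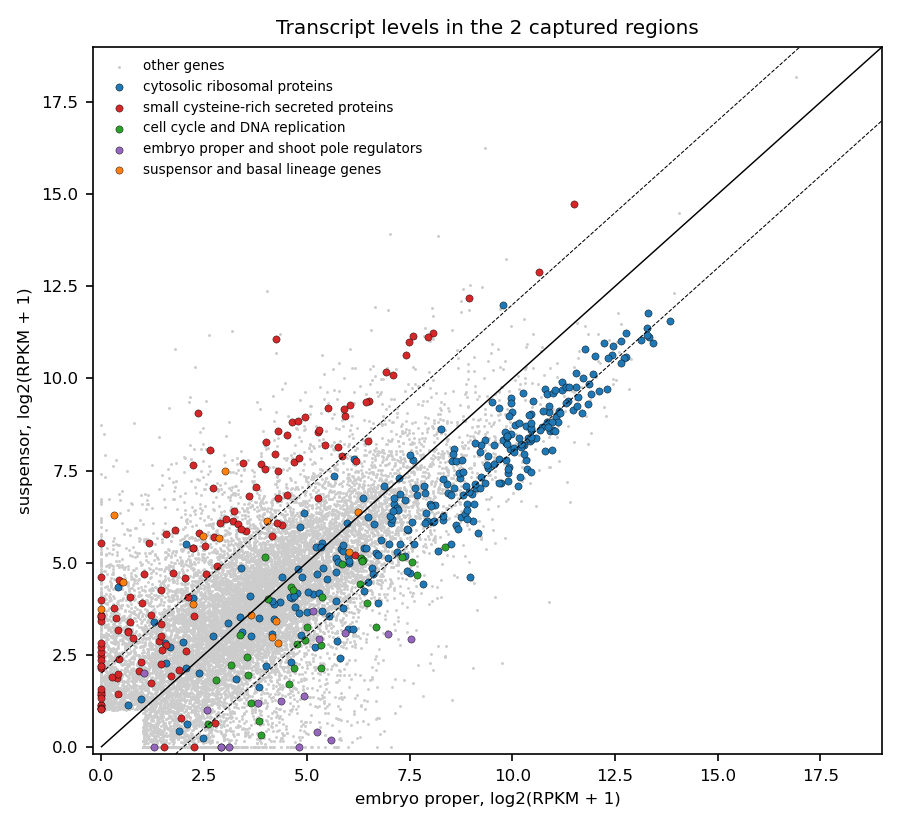
Each point is a gene with at least 1 RPKM in at least 1 library, placed by log2(RPKM + 1) in the embryo proper (x axis) and in the suspensor (y axis), with members of 5 gene lists in colour. The solid line marks equal values and the dashed lines a 4-fold difference; the 283 ribosomal protein genes lie mostly below the solid line and the 131 small cysteine-rich protein genes mostly above it.

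Regulators of the embryo proper and the shoot pole were higher in the embryo proper library. Of 17 measured members, 16 were at least 2-fold higher there and 0 were at least 2-fold higher in the suspensor. PHB (AT2G34710), a class III homeodomain-leucine zipper gene of the adaxial domain, stood at 183 RPKM in the embryo proper and 6.58 in the suspensor, 27.9-fold higher (23.3 to 33.6). AGO10 (AT5G43810), an Argonaute that protects such transcripts from microRNAs, stood at 124 and 7.31 RPKM, and WOX2 (AT5G59340), a homeobox gene of the apical lineage, at 29.7 and 1.60 RPKM. The boundary gene CUC3 (AT1G76420) was at 46.8 RPKM in the embryo proper and rested on 1 read in the suspensor, which gives 338-fold (60.4 to 13376). DRNL (AT1G24590), an AP2-type regulator of cotyledon formation, was not listed in the suspensor library and was at least 60.1-fold higher in the embryo proper, against a floor of 3 reads. The median log2 ratio of suspensor to embryo proper was −2.92, lower than in each of 10000 random lists matched on expression, and −2.62 with the unlisted members placed at that floor. It ran from −4.07 with a pseudocount of 0.1 RPKM to −1.88 with 5 RPKM.

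Genes of the root pole and the vascular precursors were divided. Of 14 measured members, 7 were at least 2-fold higher in the embryo proper and 2 in the suspensor, with a median log2 ratio of −1.08 at the percentile 0.85. SHR (AT4G37650), a regulator of ground tissue made in provascular cells, was 56.3-fold higher in the embryo proper (41.6 to 78.3), at 206 against 3.66 RPKM. TMO6 (AT5G60200), a target of the auxin response factor MONOPTEROS, stood at 89.1 RPKM in the embryo proper and 0.539 in the suspensor, where it rested on 3 reads. In the other direction, WOX5 (AT3G11260), a marker of the root pole founder cell lineage, was 2.13-fold higher in the suspensor (1.82 to 2.49), and the zinc finger gene NTT (AT3G57670) was 17.9-fold higher there (12.1 to 27.4), at 34.2 against 1.91 RPKM.

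Protoderm and cuticle genes had 8 of 16 measured members at least 2-fold higher in the embryo proper and 2 in the suspensor, and the median log2 ratio of −1.14 lay at the percentile 0.62. DCR (AT5G23940), an acyltransferase needed for cutin, stood at 333 RPKM in the embryo proper and 5.64 in the suspensor, 59.0-fold higher (45.6 to 77.5). PDF1 (AT2G42840), an epidermal marker, was abundant in both, at 5962 and 2019 RPKM. The homeobox gene PDF2 (AT4G04890) was higher in the suspensor, at 324 against 177 RPKM.

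The suspensor and basal lineage genes were higher in the suspensor library in 8 of 14 measured members and higher in the embryo proper in 2. WOX8, a homeobox gene that marks the basal lineage, stood at 77.2 RPKM in the suspensor and 0.241 in the embryo proper, a 320-fold difference (109 to 1557). PIN7 (AT1G23080), the auxin efflux carrier of the early suspensor, was 25.5-fold higher (21.8 to 30.0), at 180 against 7.06 RPKM. WRKY2 (AT5G56270), a regulator of zygote polarity, was 11.3-fold higher (9.32 to 13.8), HDG11 (AT1G73360) 7.90-fold (6.69 to 9.37) and WOX9 (AT2G33880) 4.52-fold (3.87 to 5.29). The kinase gene SSP (AT2G17090), which acts upstream of suspensor fate, stood at 12.2 RPKM and was not listed in the embryo proper library, at least 72.5-fold higher. YDA (AT1G63700), the kinase of the same pathway, went the other way, at 16.7 RPKM in the embryo proper and 6.82 in the suspensor, as did HDG12 (AT1G17920), at 18.6 and 6.07 RPKM. The median log2 ratio was 1.88, at the percentile 99.96. Endosperm and seed coat markers moved in the same direction, with median log2 ratios of 2.61 and 2.02.

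**Figure D2:**
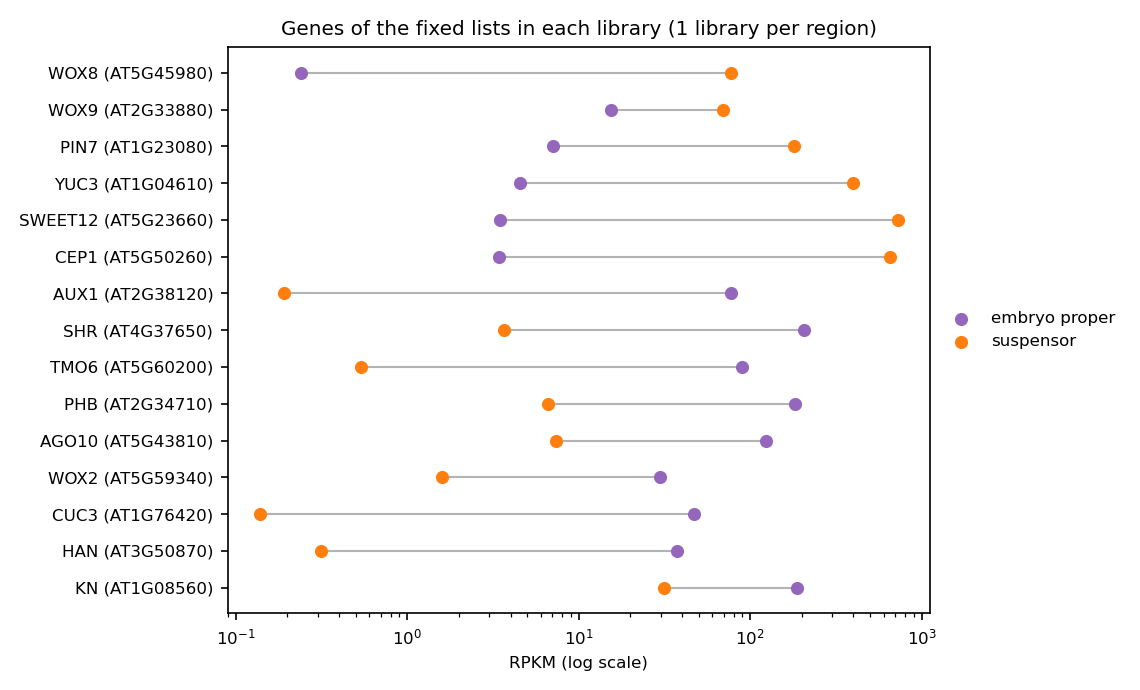
RPKM (x axis, log scale) of selected list members, chosen after their values were seen, in the embryo proper library (purple) and the suspensor library (orange), joined by a grey line; each point is 1 library. WOX8, at 0.241 and 77.2 RPKM, and CUC3, at 46.8 and 0.138 RPKM, are among the widest gaps in opposite directions.

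Genes of cell division and DNA replication were higher in the embryo proper library. Of 32 measured members, 24 were at least 2-fold higher there and 1 in the suspensor, and the median log2 ratio of −1.92 was lower than in each of the 10000 random lists. PCNA2 (AT2G29570), the replication clamp, stood at 330 RPKM against 41.6, TOPII (AT3G23890), a topoisomerase, at 205 against 24.4, and KN (AT1G08560), the cytokinesis syntaxin KNOLLE, at 188 against 31.5. The kinesin gene HIK (AT1G18370) was 11.8-fold higher in the embryo proper (10.2 to 13.8). The exception was CDKA;1 (AT3G48750), the main cyclin-dependent kinase, at 34.4 RPKM in the suspensor and 14.8 in the embryo proper.

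Histone genes and ribosomal protein genes had the same direction. Of 43 measured histone and histone-fold genes, 30 were at least 2-fold higher in the embryo proper and 7 in the suspensor, with a median log2 ratio of −2.05. HTA13 (AT3G20670), a histone H2A gene, stood at 767 RPKM against 45.3. Of 283 genes picked by ribosomal protein names that state no organelle, 192 were at least 2-fold higher in the embryo proper and 13 in the suspensor. Their median log2 ratio was −1.55, and their summed level was 329645 RPKM in the embryo proper and 97328 in the suspensor. The list was meant for the cytosolic ribosome, but it may hold organelle members and leaves out some ribosomal protein genes, such as AT3G60245. The histone and ribosomal medians were both lower than in each of the 10000 random lists. Pentatricopeptide repeat genes, most of whose products process organelle RNA, had a smaller shift, with 60 of 228 members at least 2-fold higher in the embryo proper, 18 in the suspensor and a median log2 ratio of −0.48, also lower than in each random list.

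Auxin genes were divided by paralogue, with 8 of 18 measured members at least 2-fold higher in each library. In the embryo proper, the influx carrier AUX1 (AT2G38120) stood at 77.1 RPKM against 0.191 in the suspensor, where it rested on 2 reads. In the suspensor, YUC3 (AT1G04610), a flavin monooxygenase of auxin synthesis, stood at 399 RPKM against 4.55, 87.8-fold higher (70.0 to 112). Its relatives YUC9 (AT1G04180) and YUC11 (AT1G21430) were also higher in the suspensor, at 14.8 and 9.34 RPKM, whereas YUC1 (AT4G32540) and YUC4 (AT5G11320) were higher in the embryo proper, at 8.65 and 13.0 RPKM. The aminotransferases of the preceding step were split too: TAA1 (AT1G70560) was at 16.4 RPKM in the embryo proper and TAR1 (AT1G23320) at 6.32 RPKM in the suspensor. The median log2 ratio of −0.58 was at the percentile 3.91, inside the range of random lists. With a pseudocount of 5 RPKM the list passed below the range, at a median of −0.44 and the percentile 2.05. Beside the auxin genes higher in the suspensor, the endosperm and seed coat markers were higher in that library too, with medians of 2.61 and 2.02.

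Cytokinin genes were higher in the embryo proper in 7 of 11 measured members and in the suspensor in 3, with a median log2 ratio of −1.92 at the percentile 0.01. AHP6 (AT1G80100), an inhibitor of cytokinin signalling, stood at 131 RPKM and was not listed in the suspensor library, at least 151-fold higher, and the receptor gene AHK4 (AT2G01830) was at 31.9 RPKM against 7.68. The response regulators ARR7 (AT1G19050) and ARR15 (AT1G74890) went the other way, at 19.9 and 10.1 RPKM in the suspensor against 5.57 and 2.53. Among genes with at least 10 RPKM in at least 1 library the cytokinin list lay inside the random range, with a median of −0.75; it was −1.29 without the filter and −0.76 with a pseudocount of 5 RPKM, outside that range. Gibberellin genes did not stand apart, with 2 of 7 members at least 2-fold higher in each library and a median log2 ratio of 0.44 at the percentile 66.2, while the mean was −0.29; among genes with at least 10 RPKM the median was −1.24 at the percentile 6.06. GA2OX2 (AT1G30040), an enzyme that inactivates gibberellin, was at 109 RPKM in the embryo proper and 0.271 in the suspensor, where it rested on 2 reads. GA2 (AT1G79460), an early enzyme of gibberellin synthesis, was at 62.9 RPKM in the suspensor and 12.4 in the embryo proper.

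In the list of transporters of sugars, amino acids and phosphate, 11 of 22 members were measured, so the counts do not cover each kind of transporter equally. Of the 11, 9 were at least 2-fold higher in the suspensor library and 0 in the embryo proper. SWEET12 (AT5G23660), a sucrose exporter, stood at 724 RPKM against 3.48, 208-fold higher (151 to 294), the sucrose carrier SUC5 (AT1G71890) at 177 against 4.40, and the amino acid permease AAP1 (AT1G58360) at 122 against 6.20. The median log2 ratio of 2.47 was higher than in each of the 10000 random lists, and it was 4.53 with a pseudocount of 0.1 RPKM, 4.12 among genes with at least 10 RPKM and 3.28 at 20 reads. The endosperm markers, a list that also holds SUC5, moved the same way with a median of 2.61, and the seed coat markers with 2.02.

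Genes for small cysteine-rich secreted proteins and genes annotated as lipid transfer proteins were mostly higher in the suspensor library, beside those same endosperm and seed coat medians of 2.61 and 2.02. Of 131 measured genes for small cysteine-rich secreted proteins, 121 were at least 2-fold higher in the suspensor and 4 in the embryo proper. The defensin-like gene AT1G77525 stood at 27441 RPKM in the suspensor and 2897 in the embryo proper, 9.47-fold higher (9.26 to 9.69), and LCR68 (AT2G02130) at 2139 and 18.1 RPKM. The median log2 ratio was 2.82, higher than in each of the random lists, and 1.71 after removal of the trend on coding length and GC content or 1.88 with a pseudocount of 5 RPKM. The summed level was 67552 RPKM in the suspensor and 7790 in the embryo proper. The list of lipid transfer proteins was picked by words in the annotation. It also takes in genes of the wider bifunctional inhibitor, lipid-transfer protein and seed storage 2S albumin superfamily, such as AT4G30880. Of its 35 measured members, 28 were at least 2-fold higher in the suspensor and 4 in the embryo proper, with a median of 2.12, higher than in each random list. This median was 0.91 without the filter, 1.07 and 3.53 with pseudocounts of 5 and 0.1 RPKM and 1.67 with unlisted members at the floor. Among them AT5G38170 stood at 15005 RPKM against 292, whereas LTP3 (AT5G59320) was at 758 RPKM in the embryo proper and 15.6 in the suspensor.

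Expansins and xyloglucan endotransglucosylases, which loosen or remodel cell walls, had 16 of 30 members at least 2-fold higher in the suspensor and 11 in the embryo proper, with a median log2 ratio of 1.38 at the percentile 99.97. EXPA23 (AT5G39280) stood at 3720 RPKM in the suspensor against 125, and XTH9 (AT4G03210) at 265 RPKM in the embryo proper against 14.7. Cytochrome P450 genes had 35 of 73 members at least 2-fold higher in the suspensor and 7 in the embryo proper, with a median of 0.94 at the percentile 99.5. CYP78A5 (AT1G13710) stood at 3866 RPKM in the suspensor against 262, and DWF4 (AT3G50660), the rate-limiting enzyme of brassinosteroid synthesis, at 43.4 RPKM in the embryo proper against 1.99. F-box genes had 75 of 196 members at least 2-fold higher in the suspensor and 31 in the embryo proper, with a median of 0.64 at the percentile 99.1. Without the filter of 1 RPKM these lists lay inside the random range, with medians of 0.25 for wall-loosening genes, 0.13 for cytochrome P450 genes and 0.23 for F-box genes. F-box genes were also inside it among genes with at least 10 RPKM, with a median of 0.24, where cytochrome P450 genes had 1.75. The endosperm and seed coat medians beside these lists were again 2.61 and 2.02.

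Markers of the neighbouring seed tissues were present in the suspensor library. All 10 measured endosperm markers were at least 2-fold higher there, with a median log2 ratio of 2.61 that was higher than in each of the 10000 random lists and ran from 1.88 to 3.34 with pseudocounts of 5 and 0.1 RPKM. ZOU (AT1G49770), a regulator of endosperm breakdown, stood at 63.5 RPKM against 3.90, 16.3-fold higher (11.98 to 22.6). The imprinted gene FWA (AT4G25530) stood at 40.1 against 5.84, and MINI3 (AT1G55600), a regulator of endosperm growth, at 36.9 against 4.42. Of 12 measured seed coat markers, 10 were at least 2-fold higher in the suspensor and 0 in the embryo proper, with a median of 2.02 at the percentile 99.98, or 1.83 with unlisted members at the floor. This median depended on the pseudocount, with 0.69 at 5 RPKM and 4.35 at 0.1 RPKM. TT1 (AT1G34790), a regulator of the inner seed coat, stood at 41.3 RPKM against 3.02, and LDOX (AT4G22880), an enzyme of pigment synthesis, at 25.7 against 0.220. Summed over each list, the suspensor library held 392 RPKM of endosperm markers and 103 RPKM of seed coat markers, against 27.0 and 5.92 in the embryo proper. Among genes with at least 10 RPKM the seed coat list lay inside the random range, with a median of 3.40 over fewer members.

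Other lists did not stand apart from random lists. Of 10 regulators of embryogenesis and maturation, 3 were at least 2-fold higher in the suspensor and 1 in the embryo proper, with a median log2 ratio of 0.15 at the percentile 55.6. L1L (AT5G47670) stood at 135 RPKM in the suspensor against 8.59, FUS3 (AT3G26790) at 131 against 25.6 and LEC1 (AT1G21970), which the histone list also holds, at 69.3 against 24.3. ABI3 (AT3G24650) went the other way, at 72.1 RPKM in the embryo proper and 7.97 in the suspensor. Seed storage and oil body genes, among them OLEO1 (AT4G25140) at 51.7 RPKM in the embryo proper against 12.3, had 4 of 13 members at least 2-fold higher in the suspensor, 5 in the embryo proper and a median of −0.82 at the percentile 3.00. Of 17 genes of DNA methylation and small RNA pathways, 5 were at least 2-fold higher in the suspensor and 4 in the embryo proper, with a median of 0.27 at the percentile 69.2. AGO9 (AT5G21150) stood at 94.4 RPKM in the embryo proper against 3.46, while the demethylase gene ROS1 (AT2G36490) stood at 127 RPKM in the suspensor against 23.7 and NRPD1 (AT1G63020), the largest subunit of RNA polymerase IV, at 30.2 against 1.298.

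Nuclear photosynthesis genes had 4 of 18 members at least 2-fold higher in the suspensor and 0 in the embryo proper, with a median log2 ratio of 0.65 at the percentile 93.2. The 3 measured genes of developmental cell death had 1 member at least 2-fold higher in each library and a median of 0.70 at the percentile 58.4. Of these, the papain-type protease gene CEP1 (AT5G50260) stood at 650 RPKM in the suspensor against 3.40, 191-fold higher (143 to 260). Heat shock and stress genes had 3 of 9 members at least 2-fold higher in the suspensor and 2 in the embryo proper, with a median of 0.08 at the percentile 42.9, which was −0.70 among genes with at least 10 RPKM. The 10 reference genes had 3 members at least 2-fold higher in each library, with a median of −0.16 at the percentile 48.2 and a mean of 0.02. Actin genes were among those that differed, ACT7 (AT5G09810) standing at 1094 RPKM in the embryo proper against 357 and ACT8 (AT1G49240) at 131 RPKM in the suspensor against 41.3.

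**Figure D3:**
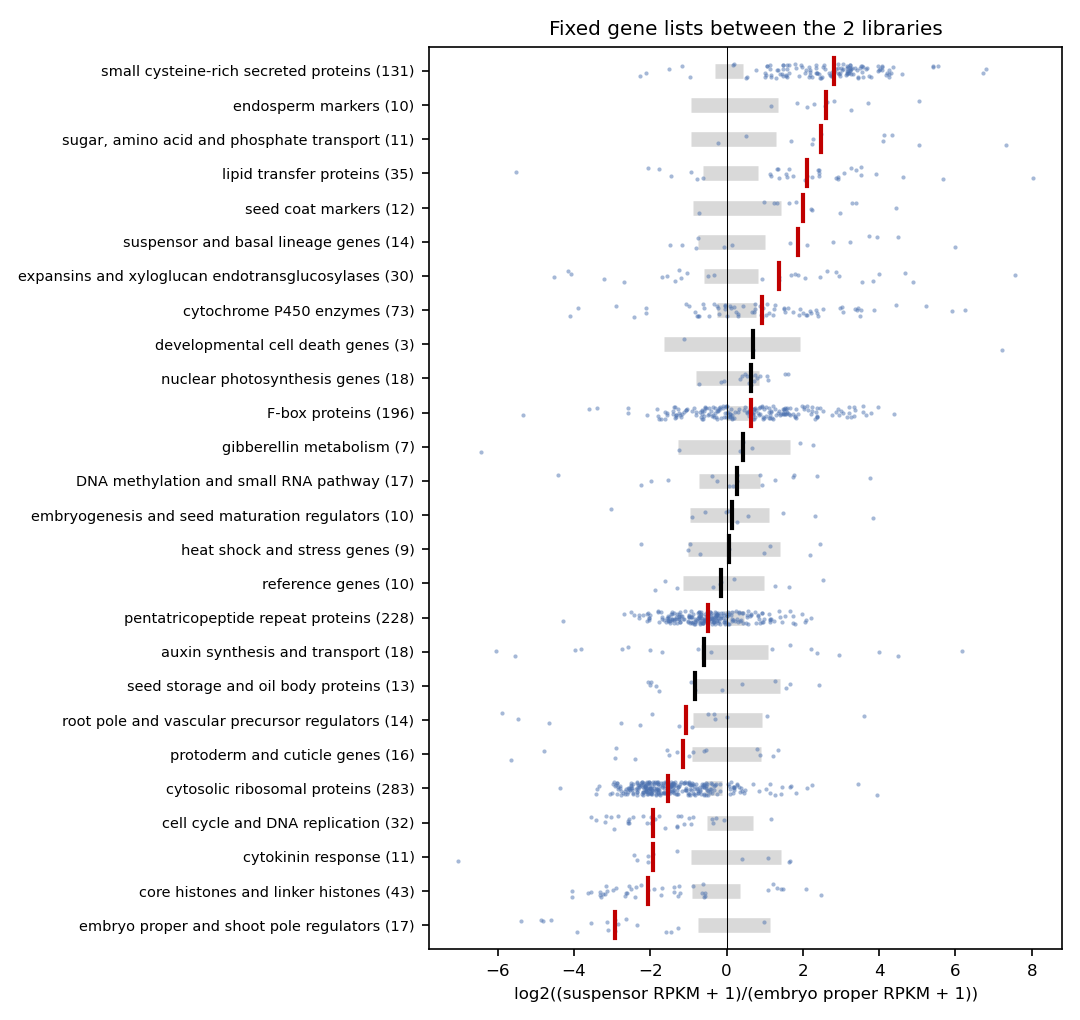
Each row is a fixed list with its number of measured members in parentheses, and the x axis is log2 of the ratio of suspensor to embryo proper with 1 RPKM added to each. Blue points are member genes, thick lines are medians (red where outside the central 95% of 10000 matched random lists, which the grey band shows), and the medians run from −2.92 to 2.82.

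Outside the lists, the nuclear protein-coding genes with the largest differences in the embryo proper direction included the aquaporin gene PIP3 (AT4G35100), at 860 RPKM against 3.80, and the arabinogalactan protein gene AGP9 (AT2G14890), at 1908 against 14.2. In the suspensor direction they included AT4G04090, a BTB/POZ domain gene, at 1783 RPKM against 2.45, the trypsin inhibitor gene TI1 (AT2G43510), at 421 RPKM and not listed in the embryo proper library, and the cupin gene AT2G28680, at 5291 against 15.4. The glutamate decarboxylase gene GAD (AT5G17330), at 168 RPKM, was also not listed in the embryo proper library and was at least 1076-fold higher in the suspensor. The most abundant transcript of both libraries was that of AT3G24250, a glycine-rich protein, with 5.11% of the reads of the embryo proper and 12.4% of those of the suspensor. AT5G61412, a protein without a described function, stood at 78011 RPKM in the suspensor and 641 in the embryo proper.

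Of the 26 lists, 17 stood outside the central 95% of random lists, 9 on the suspensor side and 8 on the embryo proper side, where 1.3 would do so by chance if lists were random draws. Among the 17, rank-based 95% intervals of the median over members included 0 for wall-loosening genes (−1.18 to 2.44) and cytokinin genes (−2.44 to 1.65). The same held for suspensor genes (−0.81 to 3.94), protoderm and cuticle genes (−2.89 to 0.79) and root pole genes (−4.64 to 0.02). Members of those lists were split in direction. The median log2 ratio of the 6984 genes with at least 10 RPKM in both libraries was −0.06, and it shifted to −0.20 under upper-quartile scaling and to 0.11 with the 10 most abundant genes of each library left out of the scaling. These scalings multiplied suspensor values by 0.898 and 1.127, too little to reverse the median of any list that stood apart. Region and library cannot be separated with 1 library each, and genes with near-identical copies, such as many histone genes, are uncertain because the treatment of reads with several matches is not given in the sources used here.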

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

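Chosen after the data were seen were the alternatives with unlisted genes as 0 and with the 10 most abundant genes left out of the scaling, and the minimum of 20 reads for the lists and the correlation. No paired analysis was possible because each region has 1 library and no test was run. The counts of detected genes stayed within 1.5 times of the main ones under the alternatives run for them. The 1784 genes higher in the suspensor and 1229 higher in the embryo proper became 940 and 665 with a pseudocount of 5 RPKM, 4218 and 3511 at 2-fold, and 751 and 412 at 8-fold; a larger pseudocount shrinks ratios and another threshold admits other genes by construction. Under the remaining alternatives the counts stayed within 1.5 times of the main ones, the widest being 2435 and 1693 with a pseudocount of 0.1 RPKM. Leaving out the filter could not change them, because a 4-fold call already needs more than 1 RPKM in the higher library. The suspensor share of the calls was 59.2%, and over the scalings it ran from 53.0% to 66.6%. The Pearson correlation across genes, 0.70 in the main setting, was 0.662 and 0.732 with pseudocounts of 0.1 and 5 RPKM, 0.740 without the filter, 0.539 at 10 RPKM and 0.686 at 20 reads; the cause was not tested. Some list medians inside the random range changed sign and stayed inside it: heat shock genes, 0.078 in the main setting, were at −0.081 without the filter, −0.698 at 10 RPKM, −0.062 under upper-quartile scaling and −0.310 at 20 reads; gibberellin genes, 0.440, were at −1.237 at 10 RPKM; maturation regulators, 0.153, were at −1.6e-05 under upper-quartile scaling; and reference genes, −0.156, were at 0.014 without the 10 most abundant genes in the scaling. No list that stood apart changed sign. Under alternatives, 6 list medians came inside the random range and 1 passed outside. These were, without the filter, wall-loosening genes at 0.249, cytochrome P450 genes at 0.128 and F-box genes at 0.230; at 10 RPKM, cytokinin genes at −0.752, seed coat markers at 3.397 and F-box genes at 0.244; and with a pseudocount of 5 RPKM, auxin genes at −0.441. Cell death genes had too few members at 10 RPKM to give a median. The filters change how many members are measured, and otherwise the cause was not tested. Depth limits low genes: a median of 88 reads per listed gene in the suspensor leaves folds of genes with 1 to 3 reads, such as CUC3 and TMO6, with wide intervals.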

Other observations

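The gene families in the next paragraph were chosen after the data had been seen, as were the tests of a single outside source, of carried suspensor RNA and of shared reads; the tests of coding length, GC content and abundant genes were set before their results were seen.

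Plasma membrane aquaporins were higher in the embryo proper library, with 5 of 8 measured members at least 2-fold higher there, 1 in the suspensor and a median log2 ratio of −4.35. Arabinogalactan proteins, heavily glycosylated proteins of the cell surface, had 15 of 28 members at least 2-fold higher in the embryo proper and 5 in the suspensor, and kinesins, motors of spindle and phragmoplast, 18 of 27 against 3. The suspensor library was at least 2-fold higher for 23 of 24 S1-type self-incompatibility proteins, with 0 in the other direction, and for 27 of 33 amino acid transporters against 3. The S1-type proteins also belong to the list of small cysteine-rich proteins, and the amino acid transporters include AAP1, AAP8 and AUX1 of the fixed lists. Their counts therefore repeat part of the results above. It was likewise higher for 16 of 27 MATE efflux proteins against 3, 13 of 18 X8 domain proteins, which bind callose, against 2, and 11 of 17 LOB domain transcription factors against 4. Proteins with a DUF239 domain were split, with 16 of 25 at least 2-fold higher in the suspensor and 9 in the embryo proper. These families were picked because their members stood out, so their counts are not independent evidence of a direction, and the suspensor groups moved beside endosperm and seed coat marker medians of 2.61 and 2.02.

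Transcripts of small cysteine-rich proteins and of endosperm markers were higher in the suspensor library: among members selected for at least 10 RPKM and a fold of at least 2, the median fold was 9.86 for 79 small cysteine-rich proteins and 10.4 for 6 endosperm markers, with 11.3 for 7 suspensor and basal lineage genes and 74.2 for 3 seed coat markers. RNA carried evenly from the suspensor would bring each of its transcripts into the embryo proper library at the same share. However, 115 abundant suspensor genes outside these lists had folds whose lower counting limit exceeded 16.5, the upper quartile of the small cysteine-rich proteins. Abundant meant at least 100 RPKM. These values argue against even carrying as the source of the small cysteine-rich transcripts in the embryo proper library. Uneven carrying is not excluded, because the suspensor library also held endosperm and seed coat markers, whose RNA need not be carried at that share. Removing the trend on coding length and GC took the median log2 ratio of the small cysteine-rich proteins from 2.82 to 1.71. For the endosperm markers it went from 2.61 to 2.39. Over 16862 genes the trend explained 2.35% of the variance of the log2 ratio. It may account for part of the difference of the small cysteine-rich proteins but not the whole. Whether 1 outside source, such as endosperm around the embryo, was captured in both libraries in different amounts cannot be told apart from other causes: the interquartile range of the small cysteine-rich log2 ratios, 1.16, lay at the percentile 0.09 of matched random lists with the same selection, but a single source would keep 1 ratio, while the folds ran from 2.83 to 130 and the median counting error was 0.21 on the log2 scale, with amplification noise unknown. Expression of these genes in the suspensor itself stays open and untested. Laser capture is meant to exclude endosperm, but that is an aim and not a measurement of what was captured. The endosperm list's own range lay at the percentile 40.5, but it rested on 6 members, with matched random ranges from 0.23 to 3.09. It could therefore not tell a single source from several. The endosperm markers SUC5 and ZOU stood at 177 and 63.5 RPKM in the suspensor, against 27441 for the defensin-like AT1G77525. That gap does not decide either, because the level of AT1G77525 in endosperm was not measured here.

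Ribosomal protein, histone and cell cycle transcripts were higher in the embryo proper library. With the trend on coding length and GC removed, the highest of the 3 medians was −1.58, and with the 10 most abundant genes left out of the scaling it was −1.38, so neither explains the whole pattern. The difference between the regions stays open and untested, as does a difference in RNA quality or amplification between single libraries.

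AT3G24250, a gene for a glycine-rich protein, held 5.11% of the reads in the embryo proper and 12.4% in the suspensor. Its coding sequence had 0 other alignments of at least 50 bases in the reference genome, which argues against reads shared with another copy. A comparison of its fold of 2.43 with the lowest fold among the small cysteine-rich proteins, 2.83, was also made and set aside, because the 2-fold selection of those members fixes that bound. No biological explanation was tested.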
